A study of Oreochromis niloticus with 6 samples.

How the data were processed

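The data were single-cell RNA counts from the gut of Nile tilapia, in 3 libraries of a probiotic-treated and 3 of an untreated group, which the labels number 1 to 3 and call biological replicates. Libraries were made with the 10x Genomics 3′ kit (version 3), per the labels' protocols. This kit captures single cells in droplets and reads the 3′ end of each transcript with a UMI, so that copies made by PCR count once. Per the submitters' processing notes, bcl2fastq 5.0.1, Cell Ranger and Seurat 4.1.0 were used, with no role or order stated. The genome build and annotation behind the counts are not given in the sources used here, so no coordinates are printed. The deposited values are UMI counts per gene and cell, whole numbers that were not normalized. Every deposited cell had at least 500 UMIs. The 6 libraries named 33921 genes in all, of which 21314 were named in each library. A gene not named in a library was taken as a count of 0 there.

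Gene symbols were those of the files. Of 23717 identifiers starting with LOC, 5982 were given a symbol through a RefSeq gene table of the assembly O_niloticus_UMD_NMBU, which was used for names alone, and 31295 identifiers matched that table. Mitochondrial genes were 37 identifiers.

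Kept cells had at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Of 39944 cells, 1634 were under the gene minimum, 13182 were over the mitochondrial limit and 26732 passed. Scrublet, run in each library with an expected doublet rate of 0.8% per 1000 cells, called 64 doublets, which were removed. It called 0 of 6697 cells in treated library 2 and few elsewhere, so doublets were in effect not removed. An alternative that removed the expected share of cells by doublet score was therefore added. The 26668 kept cells were normalized to 10000 counts and log-transformed. From 2000 variable genes chosen within libraries, mitochondrial genes left out, 30 principal components and 15 neighbours, Leiden clustering at resolution 1.0 without integration gave 38 clusters.

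Cell classes were named from 29 marker lists. A marker counted for a cluster where its level was 2-fold over that in other cells, with 20 CPM added to both sides, and at least 10% of the cluster's cells had it. Names were assigned by hand from the raised markers. A name needed 3 markers, and, for a class to be compared between groups, the 10 genes of largest fold present in at least 15% of cells must not hold more markers of another class. Clusters 4, 14, 21, 26 and 28 stayed unnamed, and clusters 11 and 22, which failed the last condition as 1 dendritic class, were kept apart. Clusters 4 and 21 each had 5 raised mesenchymal-like markers and cluster 26 had 3 T/NK-like ones, but they were left unnamed by hand. The clusters of each class mixed unequally between libraries and groups, and the names are rebuilt here, not the authors'. Cluster 4 made up 8.49% ± 9.49 of untreated and 0.643% ± 0.571 of treated cells (SD, n = 3), and its cells had 0.369 of the median UMI count of their own libraries.

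Counts were summed over all kept cells of a library and over the cells of each class in a library with at least 30 cells of it. A class was tested where at least 2 libraries of each group had them, which B-like, T/NK-like, enterocyte-like, goblet-like and mesenchymal-like cells met. Sums were tested with edgeR's quasi-likelihood test (TMM factors, its default low-count filter, no covariates), with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Fold changes are on edgeR's log2 scale, treated over untreated, with standard errors taken from the test. Cell numbers per class were tested with the same model, with the kept cells of the library as offset. Of 32 function lists, those with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and limma's fry, which tests whether a list's genes move one way on balance, were alternatives. No called list held its call with an estimated correlation. Library quality was compared with exact two-sided permutation tests, which cannot go below p = 0.1 for 3 against 3.

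The design, the marker and function lists, the filters and the rule for named genes were fixed before the data were examined. The rule took, among genes past the threshold whose groups did not overlap and whose mean was at least 20 CPM in 1 group, the 10 largest rises and the 10 largest falls that had a name, plus list members past the threshold (the 10 of smallest p where there were more). Where fewer than 5 genes passed, the 5 named genes of smallest p were taken. Cytokine, barrier and mucus genes could be named whether or not they passed. A gene with 0 UMIs in a group was given as a lower bound against a floor of 3 counts over the group. Confidence intervals of single shares are 95% Wilson intervals and the interval of the erythrocyte-like ratio is exact (Clopper-Pearson), and both cover counting error only.

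With library totals in place of TMM, the median log2 change of all genes moved by 0.18 in the whole gut, −0.20 in B-like, −0.24 in T/NK-like, −0.42 in enterocyte-like, 0.14 in goblet-like and 0.43 in mesenchymal-like cells. Changes are relative to the TMM scale. RNA free in the suspension enters every droplet, so the level of a named gene in its class was divided by that in the other cells of the same libraries. Copies of a gene that share sequence can trade counts, and whether the counting used strand is not given in the sources used here.

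The tests were tried on simulated counts with the means and library sizes of the real libraries and 200 changed genes. For 4-fold changes, edgeR recovered 2.94% in the whole gut (18152 genes), 38.2% in B-like (8581 genes), 26.5% in T/NK-like (9284 genes), 26.5% in enterocyte-like (7299 genes), 76.5% in goblet-like (7240 genes) and 0% in mesenchymal-like cells (10245 genes). For 16-fold changes the shares were 63.6%, 84.8%, 78.8%, 81.8%, 97% and 45.5%, with 6, 7, 10, 7, 11 and 6 false calls. Camera recovered the shifted list in all 6 comparisons, with 1 other list called in T/NK-like cells and 0 in the others. Genes were simulated as independent, while the estimated correlation of the real ribosomal genes was 0.943 in T/NK-like cells. The low number of false lists therefore does not carry over to the real data. A change in the share of B-like cells, as 1 of 20 categories, was recovered in 4% of 50 simulations at 8-fold, 34% at 32-fold and 56% at 128-fold. Library totals were held fixed, so the 32-fold and 128-fold changes went beyond a possible share. Most changes of that share at or under 8-fold would thus have been missed, and changes of other categories were not simulated.

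The alternatives fixed in advance were DESeq2's test, RLE size factors, library totals, no low-count filter, the replicate number as a block, each library left out in turn, stricter cells (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, the 20 most abundant genes left out, Leiden resolutions of 0.5 and 2.0, cells above the lowest library median of UMIs in their class thinned to it, other share tests and another denominator. Alternatives added after the data were seen were doublets removed by score, no mitochondrial limit, mesenchymal-like and erythrocyte-like cells left out, both libraries numbered 2 left out, cluster 4 counted as mesenchymal-like, genes lower in a class than in other cells left out, and clusters 11 and 22 as 1 category.

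Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.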

Results

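Single-cell RNA sequencing was used to compare the gut of Nile tilapia (*Oreochromis niloticus*, a farmed freshwater fish) with and without a probiotic, which the series title names as the lactic acid bacterium *Lactobacillus salivarius*. Each group held 3 libraries that the labels call biological replicates, each from gut tissue. The files held 39944 cells, and the extract protocol states the same number as the expected capture. The untreated libraries 1, 2 and 3 held 4165, 4430 and 8711 cells with 22775536, 22317601 and 36882296 unique molecular identifiers (UMIs, tags that count single transcripts). The treated libraries 1, 2 and 3 held 7977, 10057 and 4604 cells with 22102090, 32567524 and 17915657 UMIs. After filtering, 2508, 3750 and 6990 untreated and 3730, 6697 and 2993 treated cells were kept. The 2 groups differed in quality. The library median of UMIs per kept cell was 4793 ± 1569 (SD, n = 3) in untreated and 3084 ± 557 (SD, n = 3) in treated libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. The median mitochondrial share of kept cells was 4.64% ± 0.133 (SD, n = 3) in untreated and 7.38% ± 1.28 (SD, n = 3) in treated libraries, also with an exact permutation p of 0.1. Cells over the mitochondrial limit made up 24.6% ± 13.03 of untreated and 40.5% ± 10.97 of treated libraries (SD, n = 3 each, exact permutation p = 0.3). Below, levels are in CPM, the UMIs of a gene scaled to a common total for a library or for 1 cell class in it, given as mean ± SD over 3 libraries per group unless another n is stated.

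The first question was whether the cellular makeup of the gut differed between the groups. Mesenchymal-like cells, the collagen-producing and contractile cells of the gut wall, made up 52.5% ± 32.6 of untreated and 1.22% ± 0.873 of treated kept cells, a 43.2-fold lower share. The log2 difference was −5.43 (SE 1.54, edgeR adjusted p = 0.00631), and all 3 treated libraries lay below all 3 untreated ones. Unnamed clusters 4 and 21 each had 5 raised mesenchymal-like markers. Cluster 21 made up 0.167% ± 0.153 of untreated and 3.26% ± 1.68 of treated cells. Counting cluster 4 as mesenchymal-like was tried. Counting cluster 21 so, which would make the fold smaller, was not tried. Erythrocyte-like cells, which carry haemoglobin, made up 0.0143% ± 0.0248 of untreated and 4.51% ± 3.99 of treated kept cells (edgeR adjusted p = 0.00413). They numbered 3 untreated cells, all in library 3, and 570 treated cells, a ratio of the pooled shares of 188 (exact 95% interval 63.9 to 912, counting error only). Of 20 categories (named classes and unnamed clusters), 4 differed in edgeR's quasi-likelihood test, 2 higher and 2 lower in treated libraries, and 7 had an unadjusted p under 0.05. The other 2 were clusters 11 and 22, which carried the same 5 dendritic-cell markers and shared il12bb among their top 10 genes, but differed in most of those. Untreated library 2 held 95.2% of the cells of cluster 22. Whether the 2 clusters are 1 cell type split by library was not tested, so their sizes are not compared here. In 8 of the 20 categories the groups did not overlap, where chance gives 10%. The shares of a library have a fixed total, so the lower mesenchymal-like share raises others and the categories are not independent. With TMM factors over categories, 1 category was higher and 4 were lower in treated libraries.

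Enterocyte-like cells, the absorptive epithelium, made up 3.83% ± 1.64 of untreated and 21.6% ± 11.7 of treated cells, which did not pass the test (log2 difference 2.49, edgeR adjusted p = 0.184) but did without both libraries numbered 2 (3.17, adjusted p = 0.00485). B-like cells made up 4.14% ± 1.55 and 14.2% ± 10.3 (edgeR adjusted p = 0.355). T/NK-like cells, the T and natural-killer lymphocytes, made up 20.7% ± 34.9 and 32.4% ± 33.1 (edgeR adjusted p = 0.669), with 61.0% in untreated library 2 and 70.4% in treated library 2. Their log2 difference of 0.65 became 5.92 without untreated library 2 (adjusted p = 0.00113) and 4.64 without both libraries numbered 2 (0.00161). Goblet-like cells, which secrete mucus, made up 0.947% ± 0.763 and 2.64% ± 1.59 (edgeR adjusted p = 0.506). Enteroendocrine-like cells made up 0.448% ± 0.235 and 1.32% ± 0.692 (edgeR adjusted p = 0.506), and tuft-like cells, a chemosensory epithelial type, 0.0504% ± 0.0439 and 0.626% ± 0.536 (edgeR adjusted p = 0.231). Macrophage-like, acinar-like, thrombocyte-like and granulocyte-like cells had edgeR adjusted p-values of 0.669, 0.669, 0.669 and 0.811. Neural-like cells numbered 35 in untreated and 0 in treated libraries, at least 11.8-fold lower with a floor of 3 cells over the treated group, and did not pass (edgeR adjusted p = 0.0887), but did with TMM factors over categories (0.00845) or without untreated library 2 (0.0428). Cells were filtered on depth and mitochondrial share, which differed between the groups as given above. The mesenchymal call was lost without treated library 1 (adjusted p = 0.0614) or treated library 3 (0.0887), against 0.000148 to 0.0295 in its other edgeR fits. Exact permutation tests of the shares gave p = 0.1 for both classes, or 0.25 after adjustment over the 20 categories. The erythrocyte log2 difference of 7.76 became 10.47 without untreated library 3, which leaves 0 untreated cells, and 6.76 without treated library 1. That call was lost without treated library 1 (adjusted p = 0.0527), against 0.00178 to 0.0295 in the other edgeR fits that left out libraries or changed the scaling, filters, doublets or clusters.

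**Figure D1:**
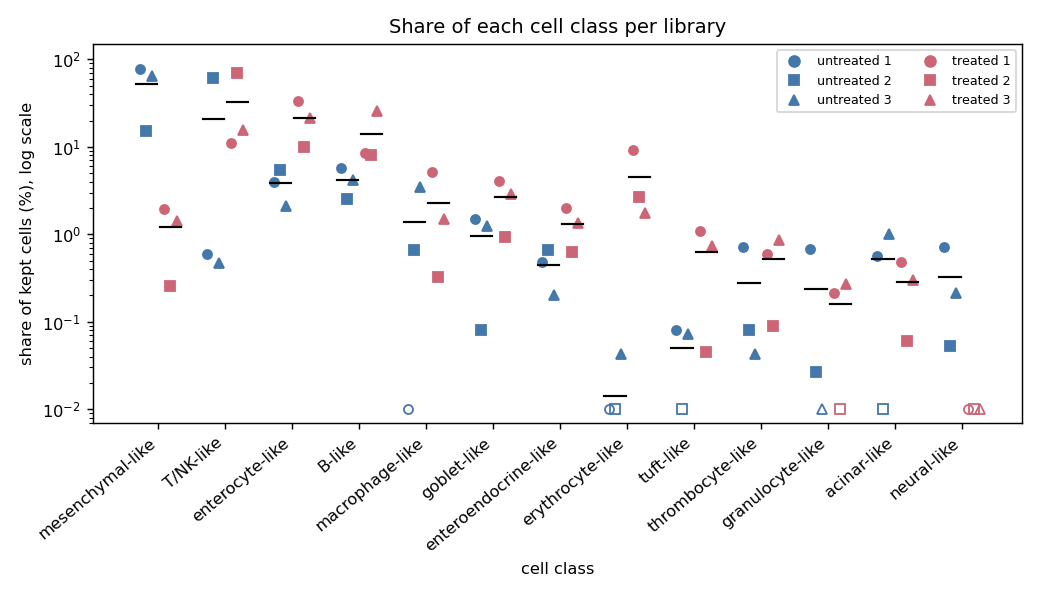
Share of kept cells (%, log axis) in each library for 13 named classes, untreated and treated, with bars at the group means and open symbols at 0.01 for a share of 0. Mesenchymal-like cells averaged 52.5% in untreated and 1.22% in treated libraries, and erythrocyte-like cells 0.0143% and 4.51%.

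Gene expression was then compared in all kept cells of each library summed. In treated libraries 23 of 36 extracellular matrix genes of connective tissue fell, and so did 9 of 35 heat-shock and dissociation-stress genes, which code for protein-folding chaperones and immediate-early factors. Camera called both lists at its preset correlation, but with an estimated correlation the adjusted p was 0.884 for each. Of the matrix genes, 23 fell and 0 rose (33 and 0 when adjusted over the list alone), including col4a1, a basement membrane collagen, at 6.40 ± 4.90 CPM in treated and 306 ± 156 CPM in untreated libraries (log2 change −5.90, SE 0.915, edgeR adjusted p = 0.0358). Tenascin C, tnca, stood at 0.742 ± 0.398 and 329 ± 181 CPM (log2 change −9.06, SE 0.884, edgeR adjusted p = 0.0348), and col6a2 at 20.2 ± 5.17 and 472 ± 298 CPM. Outside the list, the smooth-muscle genes lmod1 and tpm2 fell, with log2 changes of −8.62 (SE 0.924) and −8.14 (SE 1.2, edgeR adjusted p = 0.0348 for each). These genes mark mesenchymal-like cells, whose share fell 43.2-fold in the same libraries.

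Of the heat-shock and stress genes, 9 fell and 0 rose in the whole gut (21 and 0 adjusted over the list alone). The chaperone hsp90aa1.2 stood at 505 ± 300 CPM in treated and 8928 ± 4081 CPM in untreated libraries (log2 change −4.38, SE 0.621, edgeR adjusted p = 0.0348). The co-chaperone genes dnajb1 and bag3 fell, with log2 changes of −3.70 (SE 0.716, edgeR adjusted p = 0.0414) and −6.21 (SE 0.857, edgeR adjusted p = 0.0348). The inducible chaperone hspa1b fell from 17874 untreated to 16 treated UMIs (log2 change −10.03, SE 0.978, edgeR adjusted p = 0.0348). Of the untreated ones, 17762 came from mesenchymal-like cells. Members of the hsp70 and hsp90 families have near-identical copies, so the split of counts among them is uncertain. The feedback inhibitors of inflammatory signalling socs3 and nfkbia fell, with log2 changes of −3.14 (SE 0.688, edgeR adjusted p = 0.0497) and −1.51 (SE 0.315, edgeR adjusted p = 0.0458). Among genes that rose were fabp6, the ileal bile acid-binding protein, at 2302 ± 907 against 62.8 ± 42.2 CPM (log2 change 4.89, SE 0.844, edgeR adjusted p = 0.0383), and the chemokine gene ccl25a, at 304 ± 133 against 53.5 ± 8.01 CPM (2.29, SE 0.405, edgeR adjusted p = 0.0388). The glycolytic enzyme gapdh rose by 2.55 (SE 0.501, edgeR adjusted p = 0.0418) and the mitochondrial regulator ppargc1a by 2.33 (SE 0.411, edgeR adjusted p = 0.0388). Both fabp6 and gapdh are among the top 10 genes of enterocyte-like cluster 2, which held 2, 0 and 15 untreated and 959, 244 and 433 treated cells. The apolipoprotein gene apo14kda had 0 treated and 9692 untreated UMIs, at least 2570-fold lower with a floor of 3 counts over the group (edgeR adjusted p = 0.0388). It is a top gene of mesenchymal-like cluster 6, as is hspa1b.

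Of 18687 genes tested in the whole gut, 176 were higher and 979 lower in treated libraries, 1155 in all, and 4369 had an unadjusted p under 0.05. The groups did not overlap in 26.8% of genes, against 10% by chance. Of 30 fixed lists, limma's camera called 4. They were extracellular matrix (lower, adjusted p = 4.83e-25), heat shock and stress (lower, 5.01e-08), haemoglobin and erythroid (higher, 8.01e-05) and phagocyte oxidase, lysosome and phagosome (higher, 0.0189), each with adjusted p = 0.884 with an estimated correlation. The 5 erythroid genes had 0 rises over all genes and 4 adjusted over the list alone, beside the higher erythrocyte-like share, and the 29 lysosome and phagosome genes had 0 rises by either count. Tight junction and barrier genes (23 genes, camera adjusted p = 0.256), goblet secretion and mucus genes (8 genes, 0.189) and pro-inflammatory cytokine genes (15 genes, 0.994) were not called. With mesenchymal-like and erythrocyte-like cells left out, edgeR called 0 genes (1450 at an unadjusted p under 0.05). Of the named genes still tested there, 33 kept direction but lost the call (hsp90aa1.2, whole gut, at −4.10). The matrix gene col12a1b turned from −3.51 to 0.52 on the log2 scale. edgeR called 0 genes without untreated library 1 or 3 or any 1 treated library (3408 to 3675 at an unadjusted p under 0.05), 4488 without untreated library 2, 4023 without both libraries numbered 2 and 507 with other size factors (RLE), while DESeq2 called 3603 in all libraries.

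In B-like cells, single chaperone genes fell. The heat-shock and stress list as a whole was not called (27 genes, 3 lower and 0 higher, 9 lower and 6 higher adjusted over the list alone, camera adjusted p = 0.447), and its median log2 change was 0.25 while its mean and test pointed down. The chaperone hsp90aa1.2 stood at 264 ± 121 CPM in treated and 11940 ± 3088 CPM in untreated libraries (log2 change −5.18, SE 0.508, edgeR adjusted p = 0.00617). The gene hspa4a, of an hsp70-related exchange factor, stood at 38.6 ± 6.82 and 1766 ± 677 CPM (−5.26, SE 0.385, edgeR adjusted p = 0.00428). The co-chaperones dnaja and dnajb1 fell, with log2 changes of −5.19 (SE 0.404, edgeR adjusted p = 0.00428) and −4.74 (SE 0.56, edgeR adjusted p = 0.0138), and so did hspbp1, of an hsp70-binding protein (−4.91, SE 0.402, edgeR adjusted p = 0.00428). The ubiquitin hydrolase gene uchl1 fell by 6.02 (SE 0.733, edgeR adjusted p = 0.0154). In the untreated libraries, bag3 in B-like cells had 0.228 and dnajb1 0.567 of the level in other cells, and the others named had 0.875 to 4.06 times that level.

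In all, 10 genes were higher and 36 lower of 9158 tested in B-like cells, with 1289 at an unadjusted p under 0.05. The groups did not overlap in 18% of genes, against 10% by chance. The 10 that were higher had no symbol in the sources used here. Limma's camera called 4 of 25 lists. Cell cycle genes were lower (31 genes, camera adjusted p = 2.02e-06) and nuclear-encoded oxidative phosphorylation genes were lower (44 genes, 0.00511), with adjusted p = 0.994 for each with an estimated correlation. Mitochondrially encoded genes were higher (13 genes, camera adjusted p = 0.00404), with adjusted p = 0.994 with an estimated correlation, beside the higher mitochondrial share of treated cells. Tight junction and barrier genes were higher (6 genes, camera adjusted p = 0.000289), with adjusted p = 0.816 with an estimated correlation, but at 0.0446 (epcam) to 0.735 (cldn12) of their level in other cells of the treated libraries. Over all genes, 0 members of these 4 lists passed, and 4 tight junction and 5 mitochondrially encoded genes rose when adjusted over the list alone. The most populous B-like cluster was cluster 8, with 31 to 133 cells in untreated and 106 to 468 in treated libraries, while cluster 27 held 62 and 167 cells in untreated libraries 2 and 3 and cluster 13 held 189 to 309 in each treated library. edgeR called 0 genes without both libraries numbered 2 (575 at an unadjusted p under 0.05), 14 to 28 without any 1 library, 699 without a low-count filter (384 higher and 315 lower) and 23 (3 higher and 20 lower) among genes not lower in the class than in other cells, while DESeq2 called 247 (131 higher and 116 lower).

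In T/NK-like cells, compared over 3 treated and 2 untreated libraries because untreated library 1 held too few, single chaperone genes fell. The heat-shock and stress list was not called (28 genes, 2 lower and 0 higher, 6 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0637), with a median log2 change of 0.30 and a mean of −0.45. The level of hsp90aa1.2 was 114 ± 53.2 CPM (n = 3) in treated and 8636 ± 2058 CPM (n = 2) in untreated libraries (log2 change −6.16, SE 0.5, edgeR adjusted p = 0.00483), and that of dnajb1 107 ± 9.74 and 2958 ± 413 CPM (−4.65, SE 0.377, edgeR adjusted p = 0.00483). The gene hspa4a (−4.12, SE 0.373, edgeR adjusted p = 0.00691), the hsp90 activator ahsa1a (−3.51, SE 0.358, edgeR adjusted p = 0.0121) and the kinase-loading co-chaperone cdc37 (−2.68, SE 0.347, edgeR adjusted p = 0.0428) also fell. The tetraspanin gene cd9r rose from 48.5 ± 21.8 to 242 ± 32.7 CPM (2.42, SE 0.347, edgeR adjusted p = 0.0497). The secretory-cell genes agr2 and insl5a also rose (edgeR adjusted p = 0.0205 and 0.0497), but at 0.0309 and 0.0265 of their level in other cells of the treated libraries, and agr2 had 3 untreated UMIs.

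Of 9837 genes tested in T/NK-like cells, 8 were higher and 20 lower, with 1030 at an unadjusted p under 0.05, and 27% did not overlap between groups, where chance gives 20% for 3 against 2. Limma's camera called 3 of 25 lists, each with adjusted p = 0.888 with an estimated correlation. Cell cycle genes were lower (33 genes, camera adjusted p = 8.58e-11, 4 falling adjusted over the list alone), interferon response genes were higher (12 genes, 0.00705) and mitochondrially encoded genes were higher (13 genes, 3.54e-05, 2 rising adjusted over the list alone), the last beside the higher mitochondrial share of treated cells, and over all genes 0 members passed. The libraries drew unequally on the clusters of the class. Untreated library 2 had 772, 881 and 402 cells in clusters 7, 10 and 20, and treated library 2 had 2293 and 1428 in clusters 0 and 5. Cluster 7 also held 31 cells of untreated library 3 and 204, 161 and 119 of treated libraries 1, 2 and 3. edgeR called 6 genes without untreated library 2, where 1 untreated library of 33 such cells was left and the treated ones alone gave the spread, 125 without treated library 1 (74 higher and 51 lower), 529 without a low-count filter (278 and 251), 17 with RLE size factors or with the 20 most abundant genes left out, and 16 among genes not lower in the class than in other cells, while DESeq2 called 115 (70 and 45).

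In enterocyte-like cells, 8 of 18 genes of lipid absorption and lipoprotein assembly fell and 0 rose (11 and 1 adjusted over the list alone), while 14 of 78 cytosolic ribosomal protein genes and 12 of 44 nuclear-encoded oxidative phosphorylation genes rose. Camera called these 3 lists at its preset correlation, but with an estimated correlation the adjusted p was 0.536, 0.536 and 0.446. The summed level of the 8 fallen lipid genes was far lower in untreated library 3 than in untreated libraries 1 and 2, as given below. The lipoprotein component apoa4a stood at 46.8 ± 39.6 CPM in treated and 4308 ± 4110 CPM in untreated libraries (log2 change −5.82, SE 1.3, edgeR adjusted p = 0.0422), apoa4b at 1.82 ± 0.224 and 439 ± 509 CPM (−7.24, SE 1.35, edgeR adjusted p = 0.0333) and the lipoprotein receptor scarb1 at 22.4 ± 11.96 and 1152 ± 954 CPM (−5.08, SE 1.14, edgeR adjusted p = 0.0434). The fatty acid-binding protein gene fabp2 (−6.60, SE 1.55, edgeR adjusted p = 0.0458) and the lipid transfer protein gene mttp (−3.33, SE 0.808, edgeR adjusted p = 0.0478) fell with groups that overlapped. Of 21 genes of fatty acid oxidation and PPAR targets, 4 fell and 0 rose, by either count, among them cpt1ab, which gates fatty acid entry into mitochondria (13.1 ± 2.82 against 353 ± 242 CPM, −4.25, SE 0.62, edgeR adjusted p = 0.029), and pdk4, an inhibitor of pyruvate oxidation (−1.90, SE 0.376, edgeR adjusted p = 0.0365). That list was not called by camera (adjusted p = 0.355, median 0.12, mean −0.41).

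The 12 oxidative phosphorylation genes that rose, with 0 falling (35 and 0 adjusted over the list alone), included the ATP synthase subunit atp5mc1, at 354 ± 56.4 in treated and 151 ± 38.3 CPM in untreated enterocyte-like cells (1.64, SE 0.289, edgeR adjusted p = 0.0314), and cyc1 of respiratory complex III (1.79, SE 0.346, edgeR adjusted p = 0.0342). The 14 ribosomal protein genes that rose, with 0 falling (72 and 0 adjusted over the list alone), included rpl12 at 2655 ± 270 and 959 ± 182 CPM (1.83, SE 0.378, edgeR adjusted p = 0.0374). Copies of ribosomal protein genes make their counts uncertain. With library totals in place of normalization factors, the oxidative phosphorylation list had 0 rises and the ribosomal list 11, and both stayed higher as lists. The antioxidant enzyme gene gpx1b rose to 687 ± 283 from 241 ± 56.5 CPM (1.90, SE 0.409, edgeR adjusted p = 0.0396), and the amino acid transporter slc7a9 fell by 1.96 (SE 0.44, edgeR adjusted p = 0.043). Of 27 heat-shock and stress genes, 5 fell and 1, the transcription factor gene klf2, rose (the same numbers adjusted over the list alone). The fallen chaperones included hsp90aa1.2, at 233 ± 226 against 7620 ± 1744 CPM (−4.43, SE 0.841, edgeR adjusted p = 0.0333), and bag3, which fell by 4.77 (SE 0.548, edgeR adjusted p = 0.0181). Outside that list, dnaja stood at 11.9 ± 5.93 and 810 ± 18.95 CPM (−5.71, SE 0.487, edgeR adjusted p = 0.0164). The posterior body-axis gene hoxc9 had 130 treated and 0 untreated UMIs, at least 7.81-fold higher with a floor of 3 counts over the group (edgeR adjusted p = 0.0333). The goblet gene agr2 rose (4.21, SE 0.671, edgeR adjusted p = 0.029) at 0.0794 of its level in other cells.

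Of 7538 genes tested in enterocyte-like cells, 251 were higher and 326 lower, 577 in all, with 2139 at an unadjusted p under 0.05. The groups did not overlap in 33.2% of genes, against 10% by chance. With library totals the split was 65 higher and 534 lower, since that scaling moved the median of all genes by −0.42 on the log2 scale. Limma's camera called 7 of 23 lists. Lower were lipid absorption and lipoprotein (camera adjusted p = 2.43e-05), heat shock and stress (0.00463) and amino acid, peptide and sugar transport (12 genes, 1 lower, 0.048). Higher were oxidative phosphorylation (8.86e-13), ribosomal proteins (8.19e-19), glycolysis (13 genes, 1 higher, 0.00905) and the tricarboxylic acid cycle (22 genes, 0 higher, 0.0357). With an estimated correlation the adjusted p was 0.536 for the heat-shock list and 0.446 for the transport, glycolysis and tricarboxylic acid lists. The groups drew unequally on the clusters. Untreated libraries 1 and 2 had 94 and 202 cells in cluster 24, and untreated library 3 had 119 in cluster 12. Cluster 12 also held 164, 265 and 177 cells of treated libraries 1, 2 and 3. Treated libraries had 959, 244 and 433 in cluster 2, whose cells had a median of 1224 UMIs and a mitochondrial share of 12.6%. edgeR called 0 genes without untreated library 1, treated library 2 or treated library 3 (1322 to 1973 at an unadjusted p under 0.05), 5 without untreated library 2, 16 without treated library 1, 988 without untreated library 3 and 0 without both libraries numbered 2 (1351). With the replicate number as a block it also called 0 (1797 at an unadjusted p under 0.05). It called 241 with stricter cell filters, 951 with deeper cells thinned to the lowest library median and 1572 without a low-count filter, while DESeq2 called 931 in all libraries.

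**Figure D2:**
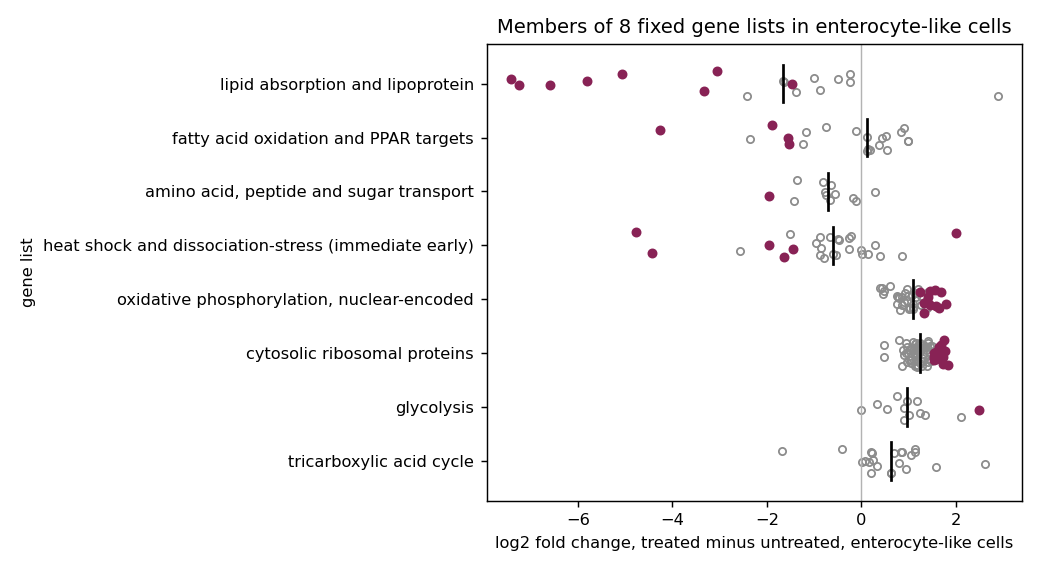
Log2 change (treated over untreated) of each measured member of 8 fixed lists in enterocyte-like cells, filled where the adjusted p was under 0.05 and open otherwise, with a black bar at the list median. Of the lipid absorption genes 8 fell, and of the oxidative phosphorylation and ribosomal genes 12 and 14 rose.

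In goblet-like cells, compared over 3 treated and 2 untreated libraries because untreated library 2 held too few, the transcription factor genes klf2 and klf4 rose while chaperone, collagen and cytokine genes fell. The level of klf2 was 805 ± 51.1 CPM (n = 3) in treated and 151 ± 25.5 CPM (n = 2) in untreated libraries (log2 change 2.29, SE 0.216, edgeR adjusted p = 0.00219), and that of klf4, which acts in goblet cell differentiation, 235 ± 27.1 and 46.8 ± 12.7 CPM (2.22, SE 0.252, edgeR adjusted p = 0.0049). The endothelial lipase gene lipg rose by 2.01 (SE 0.35, edgeR adjusted p = 0.0276). Of 28 heat-shock and stress genes, 6 fell and 2, klf2 and klf4, rose (12 and 6 adjusted over the list alone), with hsp90aa1.2 at 1189 ± 334 and 10030 ± 1450 CPM (−3.19, SE 0.273, edgeR adjusted p = 0.00206). Of 10 matrix genes, 7 fell and 0 rose (9 and 0 adjusted over the list alone), among them col1a1 (−4.30, SE 0.871, edgeR adjusted p = 0.0468) and col1a2 (−4.69, SE 0.819, edgeR adjusted p = 0.0278), whose untreated levels in the class were 0.056 and 0.0462 of those in other cells. The matrix gene tnca had 0 treated UMIs, at least 30.3-fold lower with a floor of 3 counts over the group (edgeR adjusted p = 0.0106). Of 5 cytokine and chemokine genes, 3 fell and 0 rose by either count. These were tnfb, of the tumour necrosis factor family (−3.15, SE 0.529, edgeR adjusted p = 0.023), ccl19a.1 (−1.96, SE 0.272, edgeR adjusted p = 0.0113) and cxcl12a, with 0 treated UMIs, at least 25.7-fold lower (edgeR adjusted p = 0.0164). Their levels in untreated goblet-like cells were 0.115, 0.385 and 0.0727 of those in other cells.

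Of 7474 genes tested in goblet-like cells, 30 were higher and 119 lower, 149 in all, with 1184 at an unadjusted p under 0.05, and 35.6% did not overlap between groups, where chance gives 20%. With library totals the split was 40 higher and 87 lower, with the median of all genes moved by 0.14. Limma's camera called 6 of 25 lists. Lower were extracellular matrix (adjusted p = 6.53e-19) and cytokines (4.45e-05), both with adjusted p = 0.224 with an estimated correlation, and heat shock and stress (0.000146), with adjusted p = 0.508 with an estimated correlation. Cell cycle genes (24 genes, 1 lower, 0.00299) and ribosomal protein genes (78 genes, 0 lower, 5.74e-05) were also lower and mitochondrially encoded genes (13 genes, 1 higher, 0.001) were higher, each with adjusted p = 0.855 with an estimated correlation, the last beside the higher mitochondrial share of treated cells. The goblet secretion and mucus list was not called (8 genes, 0 changed, camera adjusted p = 0.652). edgeR called 24 genes without untreated library 3, where 1 untreated library was left and the treated ones alone gave the spread, 49 without treated library 3, 84 without treated library 2, which leaves the same libraries as leaving out both numbered 2, 752 without a low-count filter, 96 with deeper cells thinned to the lowest library median and 82 among genes not lower in the class than in other cells.

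**Figure D3:**
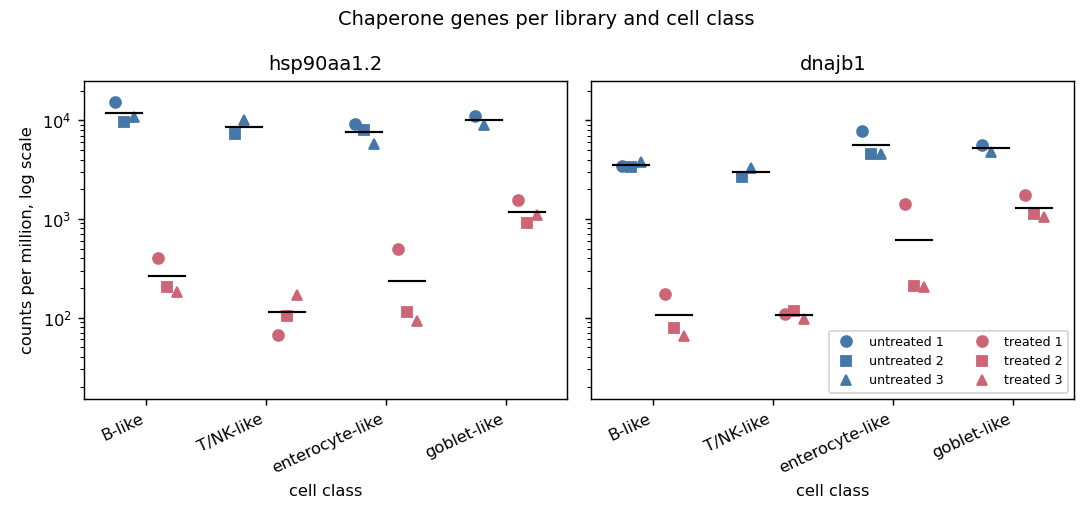
Level of hsp90aa1.2 and dnajb1 (CPM, log axis) in each library with enough cells, in B-like, T/NK-like, enterocyte-like and goblet-like cells, with bars at the group means. In B-like cells hsp90aa1.2 averaged 11940 CPM in untreated and 264 CPM in treated libraries, and in goblet-like cells 10030 and 1189.

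In mesenchymal-like cells, compared over 2 treated and 3 untreated libraries because treated library 2 held too few, 3 of 11270 genes passed, 2 higher and 1 lower, with 1030 at an unadjusted p under 0.05. The secretogranin gene scg2b, of neuroendocrine granules, rose to 196 ± 261 CPM (n = 2) from 1.06 ± 0.741 CPM (n = 3), from 21 treated and 27 untreated UMIs (log2 change 6.75, SE 1.04, edgeR adjusted p = 0.0458), at 18.5 times its level in other cells of the treated libraries. It also marks enteroendocrine-like clusters 32 and 33. The call of scg2b, mesenchymal-like, was lost with the 20 most abundant genes left out (adjusted p = 0.0546), with no mitochondrial limit (0.0561), with cluster 4 as mesenchymal-like (0.148) and without treated library 1 or 3 (0.595 and 0.77). The other 2, LOC102080222 (6.17, SE 0.684, edgeR adjusted p = 0.00306) and LOC109201864 (−7.13, SE 0.962, edgeR adjusted p = 0.0163), have no symbol in the sources used here and are named after their values were seen. LOC102080222 is a top gene of erythrocyte-like cluster 17 and stood at 0.0199 of its level in other cells of the treated libraries. Values that did not pass were those of il11a, a cytokine gene (4.14, SE 0.794, edgeR adjusted p = 0.16), fabp6 (4.28, SE 0.825, edgeR adjusted p = 0.16), isyna1 (edgeR adjusted p = 0.147) and hspa1b, with 0 treated and 17762 untreated UMIs, at least 35.2-fold lower (edgeR adjusted p = 0.0959). Limma's camera called 4 of 26 lists, each with adjusted p = 0.992 with an estimated correlation. Lower were extracellular matrix (34 genes, 3 falling adjusted over the list alone, camera adjusted p = 8.51e-08), heat shock and stress (34 genes, 5 falling adjusted over the list alone, 3.16e-06) and ribosomal proteins (78 genes, 0.0208). Higher were mitochondrially encoded genes (13 genes, 0.0208), beside the higher mitochondrial share of treated cells, and over all genes 0 members of the 4 lists passed. The median of all genes was −0.42 and moved by 0.43 with library totals, under which the ribosomal list was not called (adjusted p = 0.923). Clusters 1, 3, 6 and 9 held most untreated cells of the class, and clusters 1 and 16 most treated ones. edgeR called 0 genes without treated library 1 or 3 (1214 and 1018 at an unadjusted p under 0.05), where 1 treated library was left and the untreated ones alone gave the spread, 54, 62 and 29 without untreated library 1, 2 or 3, 62 without both libraries numbered 2, 118 without a low-count filter and 9 with thinned cells, while DESeq2 called 118.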

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

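The test reported in this part was chosen after the changes within the 2 classes had been seen. The treated minus untreated change was compared between enterocyte-like and B-like cells with an interaction term in 1 edgeR quasi-likelihood fit of both classes, with the library as a block. Of 11438 genes, 13 differed between the classes, and 8 of these had log2 changes of opposite sign in the 2 classes. Among them was cpt1ab, of fatty acid entry into mitochondria, whose log2 change was −4.25 in enterocyte-like and 0.18 in B-like cells, a difference of −4.05 (edgeR adjusted p = 0.0475). Another was slc25a11, a mitochondrial carrier of oxoglutarate and malate, at 3.39 in enterocyte-like and −1.18 in B-like cells, a difference of 4.89 (edgeR adjusted p = 0.0475), with 4 untreated UMIs in enterocyte-like cells. Neither gene passed the test in B-like cells (edgeR adjusted p = 0.795 and 0.354). No technical or biological explanation of these differences was tested.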

How the results depend on the processing

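In this part, removing doublets by score, dropping the mitochondrial limit, leaving out mesenchymal-like and erythrocyte-like cells, leaving out both libraries numbered 2, counting cluster 4 as mesenchymal-like, leaving out genes lower in a class than in other cells and merging clusters 11 and 22 were chosen after the data were seen. Counts are of edgeR calls at an adjusted p under 0.05 unless another tool is named, and the causes of the moves were not tested except where fewer libraries or cells entered by construction. A named gene was counted only in the alternatives that still tested it. Over these, named genes kept direction and call in 1883 cases, kept direction but lost the call in 1008 and reversed in 1. Called lists did so in 237, 85 and 1 cases. Shares stayed on their side of the threshold in 336 cases, lost the call in 19 and gained it in 12. All 18 quality comparisons kept their sign and moved by less than the larger SD of the 2 groups.

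The whole-gut count of 1155 genes became 3603 with DESeq2, 507 with RLE factors, 4023 without both libraries numbered 2 and 0 without mesenchymal-like and erythrocyte-like cells (1450 at an unadjusted p under 0.05). There col12a1b reversed to a log2 change of 0.52, past no threshold. With 1 library left out the count ran from 0 (3408 to 3675 unadjusted, without untreated 1 or 3 or any treated library) to 4488 (without untreated 2). B-like cells (46 genes) gave 247 with DESeq2, 699 without a low-count filter, 0 without both libraries numbered 2 (575 unadjusted) and 23 without genes lower in the class, and 14 to 28 with 1 library left out. T/NK-like cells (28 genes) gave 115 with DESeq2, 17 with RLE factors, 529 without a low-count filter, 17 with the 20 most abundant genes left out and 16 without genes lower in the class, and 6 (without untreated 2) to 125 (without treated 1) with 1 library left out. Enterocyte-like cells (577 genes) gave 931 with DESeq2, 1572 without a low-count filter, 241 with stricter cells, 951 with thinned cells and 0 without both libraries numbered 2 (1351 unadjusted), and 0 (without untreated 1, treated 2 or treated 3) to 988 (without untreated 3) with 1 library left out. Goblet-like cells (149 genes) gave 752 without a low-count filter, 96 with thinned cells, 84 without both libraries numbered 2 and 82 without genes lower in the class, and 24 (without untreated 3) to 149 with 1 library left out. Mesenchymal-like cells (3 genes) gave 118 with DESeq2, 118 without a low-count filter, 9 with thinned cells and 62 without both libraries numbered 2, and 0 (without treated 1 or 3) to 62 (without untreated 2) with 1 library left out.

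With an estimated correlation, camera called 0 lists in the whole gut and 0 in each of the 5 classes. Limma's directional fry called 0 in the whole gut and in B-like, T/NK-like, goblet-like and mesenchymal-like cells, and 8 in enterocyte-like cells. Without both libraries numbered 2, camera called 7 lists in the whole gut, 8 in B-like and 9 in T/NK-like cells. With 1 library left out it called 3 to 8 lists in the whole gut, 3 to 7 in B-like, 4 to 8 in T/NK-like, 4 to 9 in enterocyte-like, 5 to 7 in goblet-like and 2 to 5 in mesenchymal-like cells. The list cytosolic ribosomal proteins, mesenchymal-like, reversed without untreated 3 (camera adjusted p = 0.59, against a lowest of 4.86e-11 without treated 1). Of the 4 share categories, 0 passed an exact permutation test, which cannot go below p = 0.1 here. There were 2 at Leiden resolution 0.5, 2 with clusters 11 and 22 merged and 8 without both libraries numbered 2. With 1 library left out there were 0 (without treated 1) to 6.

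The replicate numbers were tested as pairs. Same-numbered untreated and treated libraries correlated at 0.332, 0.443 and 0.051 in their deviations from the group means over whole-gut genes. Numbers 1 and 2 passed the bound of 0.1 and number 3 did not, and untreated 3 correlated best with treated 1 (0.297). In B-like cells the same-numbered values were 0.177, 0.084 and 0.124, and in enterocyte-like cells −0.05, 0.09 and −0.088. A pairing of all 3 numbers was thus not shown, and a pairing of some is not excluded. With the replicate block the counts were 1783 genes in the whole gut, 19 in B-like, 80 in T/NK-like, 0 in enterocyte-like (1797 unadjusted, DESeq2 without the block 931), 343 in goblet-like and 15 in mesenchymal-like cells. It gave 5 lists in T/NK-like cells and 1 share category, with an adjusted p of 0.0966 for erythrocyte-like cells.

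Stricter cells gave no value for T/NK-like and mesenchymal-like cells, and doublets kept and Leiden resolution 0.5 gave none for goblet-like cells, because too few libraries held enough cells or the class was not found. The mesenchymal-like class held 133 treated cells in all, those of treated library 2 included, which was left out of the comparison. Where a left-out library left 1 in its group (untreated in T/NK-like and goblet-like, treated in mesenchymal-like cells), the other group alone gave the spread.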

Other observations

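In this part, the tests of gut region and of doublets with mesenchymal-like cells, and the counts over other splits of the libraries, were set before their results were seen. So were the edgeR comparisons that gave the single genes, and all other tests were set after. Single genes other than those described above also changed. In treated enterocyte-like cells the phospholipase gene plb1 fell by 7.36 on the log2 scale (SE 1.3, edgeR adjusted p = 0.0315), as did insig1, a brake on cholesterol synthesis (−3.32, SE 0.637, edgeR adjusted p = 0.0342), and dspb, a desmosomal plaque gene (−2.63, SE 0.596, edgeR adjusted p = 0.0437), the last from 636 ± 418 to 70.8 ± 16.8 CPM (SD, n = 3). The sensor of oxidative stress keap1 fell by 2.55 (SE 0.394, edgeR adjusted p = 0.029). The gene gmds, of the synthesis of fucose donors for glycans, rose from 9.58 ± 4.44 to 68.9 ± 45.6 CPM (log2 change 3.12, SE 0.621, edgeR adjusted p = 0.0365), and the growth factor gene fgf7 was at 48.8 ± 20.7 against 3.59 ± 6.21 CPM, from 4 untreated UMIs (edgeR adjusted p = 0.0434).

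In treated goblet-like cells (n = 3 against 2 libraries), noct, a clock-controlled deadenylase-like gene, rose from 10.5 ± 2.45 to 72.5 ± 26.3 CPM (log2 change 2.71, SE 0.43, edgeR adjusted p = 0.0193). The fatty acid elongase gene elovl6 fell from 70.3 ± 11.5 to 18.1 ± 4.29 CPM (−2.06, SE 0.274, edgeR adjusted p = 0.00977), and the mitotic gene cenpf fell by 2.18 (SE 0.432, edgeR adjusted p = 0.0445).

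Single chaperone genes were lower in treated libraries in 4 classes, and the median log2 changes, over the fallen genes alone, were −4.74 in B-like, −4.09 in T/NK-like, −4.37 in enterocyte-like and −3.02 in goblet-like cells. A dissociation stress that moves immediate-early genes as much as those chaperones is argued against, since all measured immediate-early genes had medians of 0.64, 0.50, −0.48 and −0.26 (SD over genes 0.65, 0.55, 0.76 and 1.03). Those chaperones were picked as fallen, which widens the gap, while the immediate-early genes were not picked. Free RNA from mesenchymal-like cells is argued against, for the fallen genes as a set, by the untreated levels. Their class medians were 0.915 or more of the level in mesenchymal-like cells. Class medians of the change after thinning were 0.921 or more of the unthinned one. That fit had no low-count filter and was chosen after the filtered fit (0.974). Thinning draws UMIs at random before summing, which keeps the expected shares of genes within a cell. It therefore decides nothing about depth. What stays open is free RNA for the 11 of 41 gene and class cases under 0.5 of the mesenchymal-like level (bag3 at 0.121 in B-like cells). For all 41 cases depth, a heat or handling step of the untreated libraries that acts on chaperones, and the treatment itself also stay open. The last 2 cannot be told apart, because the labels give no handling or day, and that all 10 untreated class and library sums lay above all treated ones decides nothing, since the summed genes were picked as fallen.

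Lipid absorption genes were lower in treated enterocyte-like cells, and their summed level was 14554, 9723 and 355 CPM in untreated 1, 2 and 3 against 163, 88.9 and 73.1 in the treated libraries. Untreated 1 and 2 held 94 and 202 cells of enterocyte-like cluster 24, and every other library held 0. The raised markers of that cluster included apoa4a, fabp2, apoa4b and mttp, so the high levels in untreated 1 and 2 go with its presence. Free RNA is argued against by untreated levels at a median of 74.7 times those in other cells. That ratio is raised in part by design, since apoa4a, fabp2, apoa4b and mttp also served as markers to name the class. The change after thinning was 0.94 of the unthinned one, in a fit without the low-count filter because the filtered one kept 2 of the 8 genes. Random thinning before summing keeps the expected shares of genes within a cell, so depth stays open. A candidate explanation is that more posterior gut was sampled in the treated group. The share of hox UMIs from the posterior groups 9 to 13 in mesenchymal-like cells was higher in the treated library in 6 of 6 usable pairs, at 15.8%, 4.31% and 21.9% in untreated 1, 2 and 3 against 32.3% of 62 UMIs in treated 1 and 30% of 20 UMIs in treated 3, while treated 2 had 7 UMIs, under the minimum of 20, and the Wilson interval of treated 3 (14.5% to 51.9%) held the value of untreated 3. In enterocyte-like cells that share was 52.3%, 39.1% and 74.6% against 85.2%, 75.8% and 80.1%, and an effect of the treatment itself stays open, untested. The clusters within both classes differed between the groups, so these hox shares do not tell region from cell type. Of mesenchymal-like cells, treated 1 and 3 had 25 and 34 in cluster 16, while most untreated ones were in clusters 1, 3, 6 and 9.

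Extracellular matrix genes were lower in treated goblet-like cells. In untreated goblet-like cells 90% of the matrix genes stood within 2-fold of 1 ratio to their level in mesenchymal-like cells (median 0.042), which both free RNA and doublets with such cells give. The reading of that first test changed after it was seen, because free RNA would spread over cells by depth, while 93.0% of the 1364 matrix UMIs lay in 12 of 125 cells, against 20.7% to 24.3% in draws by depth. Doublets with mesenchymal-like cells needed a share above 50% and above those draws, and the value of 93.0% is consistent with them, as a hypothesis. Mesenchymal-like cells made up 52.5% of untreated and 1.22% of treated cells, so fewer such doublets would form in treated libraries, and a change within goblet-like cells was not tested apart from them. With the expected share of doublets removed by score, edgeR called 110 genes in goblet-like cells in place of 149. Of these, 87 were lower in place of 119 and 23 higher in place of 30, so the loss was not limited to fallen genes.

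The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The count of genes was as large in 1 of the 10 splits, the real one, for the whole gut (1155, highest other 0), B-like cells (46, highest other 1) and enterocyte-like cells (577, highest other 0), and so was the count of share categories (4, highest other 0). Counts of called lists were as large in 10 of 10 splits for the whole gut (4, highest other 14), 9 for B-like cells (4, highest other 8) and 2 for enterocyte-like cells (7, highest other 8).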
